A study of Homo sapiens with 15 samples.

How the data were processed

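RNA-seq was measured in 15 libraries from a pair of leukemia cell lines, U937 and ML1. Treatment lasted 24 h and used diluent, 10 nM prexasertib or, in U937, 10 nM prexasertib with 350 nM LSN622666, all with 5 µM Q-VD-OPh. Each of the 5 groups held 3 libraries. Groups and replicate numbers were taken from the labels, every column matched a sample, and no library was left out. Per the labels, RNA was isolated with an RNeasy kit and libraries were made with the TruSeq RNA Library Prep Kit v2, which does not mark strand. The authors deposited raw read counts per gene symbol, with no normalization. Per the labels, TopHat2 2.0.14, Bowtie2 2.2.6 and featureCounts 1.4.6 of the Subread package were used with the hg38 build. The gene annotation, the strand setting and whether mates were counted as one fragment are not given in the sources used here.

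Of the gene symbols in the file, 23900 (90.2%) were matched to GENCODE v29 on GRCh38 for coordinates, exon overlaps and lengths. Library totals ran from 49011222 to 87301014 counts, and 3 counts, the floor used for a group with none, were over a group's 3 libraries. Counting intervals and floors cover counting error only, since reads carry no molecular identifiers.

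Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the groups (17243 tested), libraries were scaled by TMM, and 1 model with a mean per group was fitted to all 15 libraries with the robust quasi-likelihood method (10 residual degrees of freedom, median biological coefficient of variation 0.163). Each contrast used edgeR's quasi-likelihood F test with Benjamini-Hochberg adjustment over all tested genes, and a gene was called at an adjusted p under 0.05. The 6 comparisons were prexasertib against diluent in each line, the combination against prexasertib and against diluent in U937, the difference of the prexasertib effect between the lines, and U937 against ML1 with diluent. The models, lists, naming rule and alternatives named for the closing comparison were fixed before the data were examined.

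The 22 gene lists, from general knowledge, hold 507 genes, all in the file (1 by an older symbol). They cover AP-1 and ATF factors, other reported TNF regulators, TNF and NF-kB targets, immediate early genes, MAPK feedback genes, the death receptor pathway, p53 targets, E2F and DNA replication, G2 and mitosis, homologous recombination and Fanconi genes, checkpoint and CDK regulators, interferon-stimulated genes, histones, and the integrated stress and unfolded protein response. Monocyte markers, myeloid progenitor and granule genes, cholesterol synthesis, ribosome biogenesis and MYC targets, NRF2 targets, heat shock genes, the BCL2 family and markers of non-myeloid cells complete them. Lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over 132 tests (22 lists in 6 comparisons). With the preset correlation 80 tests passed. With a correlation estimated from the data 0 passed in camera (34 at an unadjusted p under 0.05, smallest adjusted p 0.11), and fry, which asks whether a list's genes move one way on balance without comparing them with other genes, called 85. Member counts were adjusted over all genes and again over the list alone. Some lists overlap, so are not independent.

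Genes were named by a fixed rule. For each comparison up to 8 genes each way (5 for the difference between lines and for the diluent comparison) with the largest absolute log2 fold change were taken. They needed an adjusted p under 0.05, a mean of at least 5 CPM over the groups compared and, except for the difference between lines, no overlap between the libraries of the groups. Always named were TNF, CHEK1, CDK2 and TNFRSF1A, all AP-1 and ATF factors called in U937, and up to 4 members of each list with the smallest p. Members that moved against the rest of a list were named in addition, and those were chosen after their values were seen. Some genes that met the rule are not reported here, while list totals, medians and the closing totals still include them.

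Alternatives were DESeq2 1.42.0, DESeq2 size factors or upper-quartile factors in edgeR, no low-count filter, a stricter filter (at least 5 CPM in 3 libraries), a fit to 1 cell line or to the groups compared, a replicate block, counts thinned to the smallest library total, a threshold of 1 on the absolute log2 fold change, and leaving out each library in turn. Whether replicate numbers pair the samples was checked by correlating deviations from group means between same-numbered libraries. Over the combination and prexasertib groups the correlations were 0.409, 0.37 and 0.384, all above the limit of 0.1, so the numbers pair these groups, and in the other group pairs at least 1 correlation was lower. Replicates of a group correlated at 0.982 to 0.9937 on log2 CPM.

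The pipeline was tested on simulated data with counts drawn from the fitted means and a seeded set of genes changed. For U937 prexasertib against diluent it recovered 28.4%, 79.1% and 90.9% of genes changed 1.5-fold, 2-fold and 4-fold among 17243 genes, with 7 unchanged genes called. For ML1 it recovered 34.3%, 83.6% and 95.5%, with 5 unchanged genes called. Other scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.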

Results

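RNA-seq read counts were collected from 2 human leukemia cell lines, ML1 (a myeloid leukemia line) and U937 (a myeloid line with monocytic features), after 24 h of treatment. All cultures received the pan-caspase inhibitor Q-VD-OPh at 5 µM. The groups were diluent and 10 nM prexasertib, an inhibitor of the kinase CHK1, in each line, and in U937 also 10 nM prexasertib with 350 nM LSN622666, a compound given by code name. Each of the 5 groups held 3 libraries, no group received LSN622666 alone, and ML1 had no group with the pair of compounds. Total counts for replicates 1, 2 and 3 were 58805996, 87301014 and 56688197 in ML1 with diluent and 59249514, 59905000 and 56711831 in ML1 with prexasertib. In U937 they were 70978970, 60199237 and 49011222 with diluent, 63179353, 60826821 and 65885497 with prexasertib and 60261136, 71041896 and 81764532 with the combination. Genes with at least 1 count numbered 17606 ± 209 in ML1 with diluent and 18538 ± 328 with prexasertib (mean ± SD, n = 3). The U937 numbers were 18030 ± 353, 20328 ± 647 and 19246 ± 261 for diluent, prexasertib and combination. Of the gene symbols in the file, 17243 passed the low-count filter and were tested. Levels are library-scaled read counts (CPM) as mean ± SD over 3 libraries, changes are log2 fold changes ± standard error, and adjusted p-values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The labels do not say whether replicates were separate cultures, so these p-values measure the spread between these samples, part of which may be technical.

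The series design asks which candidate TNF transcription factors change in mRNA level, so TNF, the gene of the cytokine TNFα (chromosome 6, 31575567 to 31578336, plus strand, GRCh38), was read first. In ML1, TNF stood at 3.94 ± 1.79 CPM with diluent and 198 ± 55.5 CPM with prexasertib. In U937 it was at 2.7 ± 0.424, 16.5 ± 7.37 and 6.86 ± 3.23 CPM with diluent, prexasertib and the combination. TNF therefore rose in both lines under prexasertib, by 5.65 ± 0.44 in ML1 (adjusted p = 6.3e-08) and by 2.61 ± 0.40 in U937 (adjusted p = 0.00036), with all 3 treated libraries above all 3 diluent libraries in each line. The rise was smaller in U937, with a difference of -3.05 ± 0.55 (adjusted p = 0.00079), and the diluent levels of the lines were not told apart (log2 fold change -0.54 ± 0.40, adjusted p = 0.26). Adding LSN622666 lowered TNF relative to prexasertib alone (-1.27 ± 0.37, adjusted p = 0.02). That call ended with no low-count filter (adjusted p = 0.065), without U937 prexasertib replicate 2 (-0.86, adjusted p = 0.097), and without combination replicate 1 (-1.18, 0.075) or 3 (-1.01, 0.089). Against diluent, TNF in the combination was still higher (1.34 ± 0.40, adjusted p = 0.044). This call ended with no low-count filter (adjusted p = 0.12) and without diluent replicate 1, 2 or 3 (0.099, 0.11 and 0.13) or combination replicate 1 or 2 (0.1 and 0.15).

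**Figure D1:**
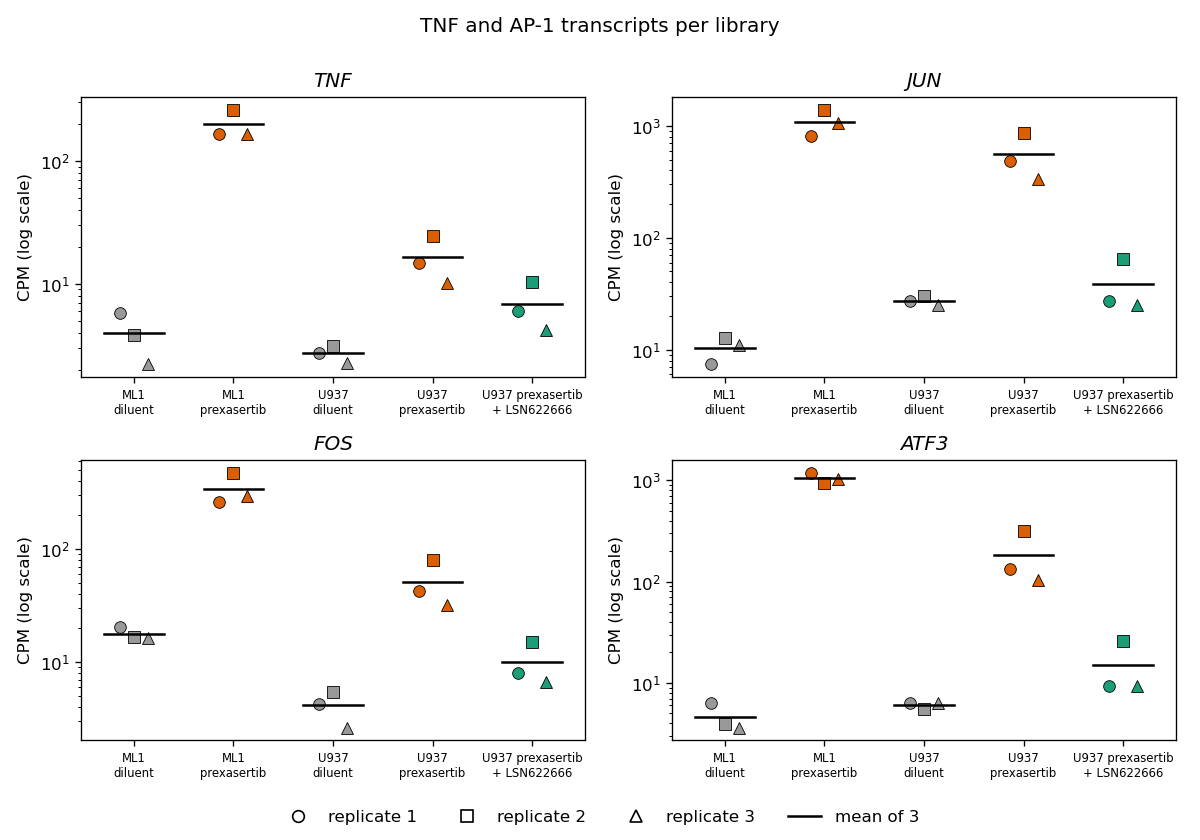
CPM (log axis) of TNF, JUN, FOS and ATF3 in each library, by group; symbols mark replicates 1, 2 and 3 and bars mark group means. Mean TNF was 198 CPM in ML1 with prexasertib, 16.5 CPM in U937 with prexasertib and 6.86 CPM in U937 with the combination.

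In U937, prexasertib raised 14 of 21 tested AP-1 and ATF factors, the bZIP proteins that bind AP-1 and CRE sites. JUN, the core AP-1 subunit (chromosome 1, 58780788 to 58784327, minus strand, GRCh38), went from 27.4 ± 2.62 CPM with diluent to 558 ± 268 CPM with prexasertib. Its dimer partner FOS went from 4.13 ± 1.44 to 51.5 ± 25.4 CPM, and ATF3, a stress-induced repressor and activator, from 6.04 ± 0.464 to 185 ± 117 CPM. JUND, an AP-1 subunit present in unstimulated cells, went from 53.9 ± 6.84 to 174 ± 34.1 CPM, and JUNB from 62.4 ± 12.5 to 180 ± 40 CPM. All 5 rose, by 4.35 ± 0.42 for JUN (adjusted p = 6.6e-06), 3.63 ± 0.40 for FOS (2.1e-05), 4.94 ± 0.49 for ATF3 (1.2e-05), 1.69 ± 0.15 for JUND (1.6e-06) and 1.53 ± 0.22 for JUNB (9.4e-05). Other factors that rose were FOSB (2.86), FOSL2 (1.44), BATF2 (3.18), ATF6, a sensor of protein folding stress (0.84), and the small MAF proteins MAFF (3.08) and MAFG (0.75). FOSL1 rose by 0.59 ± 0.18 (adjusted p = 0.018), a call that ended without diluent replicate 3 (0.11) or prexasertib replicate 1 (0.063) or 2 (0.11). ATF5 rose by 0.59 ± 0.20 (adjusted p = 0.034), a call that ended in a fit to U937 alone (0.056) and without diluent replicate 1 or 3 (0.14 and 0.13) or prexasertib replicate 2 or 3 (0.16 and 0.066). In all 14 rose and 0 fell (14 and 0 adjusted over the list alone). Their median log2 fold change was 0.84 (camera adjusted p = 1.2e-07, and 0.15 with an estimated correlation). Without prexasertib replicate 2, 12 rose and the median was 0.57, and the log2 fold changes of ATF3 and BATF2 were 4.26 and 2.23.

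Among 28 other reported regulators of TNF in U937, NFKB2 and RELB, subunits of the non-canonical NF-kB dimer, went from 43.3 ± 5.83 to 237 ± 58.2 CPM and from 12.7 ± 4.6 to 84.2 ± 27.8 CPM. EGR1, a zinc finger factor induced by MAPK signalling, went from 3.07 ± 1.39 to 58.5 ± 38.5 CPM, and KLF6 from 39.8 ± 3.02 to 236 ± 87.7 CPM. These 4 rose by 2.45 ± 0.22, 2.73 ± 0.34, 4.23 ± 0.53 and 2.57 ± 0.24 (adjusted p = 1.7e-06, 6.1e-05, 0.00012 and 2.2e-06), and without prexasertib replicate 1 the value of EGR1 was 3.55. In the list as a whole 11 rose and 2 fell (11 and 2 adjusted over the list alone). Their median was 0.30 (camera adjusted p = 0.013, and 0.25 with an estimated correlation). The 2 that fell were NFATC3 and IRF8, named after their values were seen. Without diluent replicate 1 or 3, 1 fell, and without prexasertib replicate 2, 8 rose, 0 fell and the median was 0.15. NF-kB target genes mostly rose. CXCL8, a neutrophil chemokine, went from 8.35 ± 2.4 to 202 ± 66.8 CPM, TNFAIP3, which encodes the NF-kB inhibitor A20, from 19.3 ± 6.96 to 243 ± 64.7 CPM, and BIRC3, an inhibitor of apoptosis, from 1.86 ± 0.212 to 20.3 ± 5.77 CPM. Of 27 TNF and NF-kB targets 23 rose and 1 fell (23 and 1 adjusted over the list alone), the 1 that fell being TNFAIP8 (named after its values were seen). Their median was 2.43 (camera adjusted p = 2.3e-13, and 0.13 with an estimated correlation). With prexasertib replicate 2 left out, 21 of them rose and 1 fell.

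Immediate early genes, which respond to signalling without new protein synthesis, were mostly higher in U937 after prexasertib. DUSP1, a phosphatase that switches off MAPKs, went from 2.7 ± 0.9 to 51.7 ± 15.7 CPM, KLF2 from 0.36 ± 0.0308 to 11.4 ± 6 CPM and the antiproliferative gene BTG2 from 7.16 ± 0.301 to 37.6 ± 6.88 CPM. Of 24 such genes 22 rose and 1 fell (22 and 1 adjusted over the list alone). Their median was 2.51 (camera adjusted p = 9.7e-15, and 0.13 with an estimated correlation). The 1 that fell was MYC (-0.67 ± 0.24, adjusted p = 0.041), a call that ended under upper-quartile factors (0.05), with no filter or a stricter filter (0.074 and 0.062), and without diluent replicate 1 or 2 (0.082 and 0.094) or prexasertib replicate 2 (0.17). In the MAPK feedback list, IER3, PHLDA1 and DUSP4 rose by 4.68 ± 0.59, 2.49 ± 0.30 and 1.17 ± 0.20 (adjusted p = 0.00014, 1.8e-05 and 0.00048). Of its 16 genes 12 rose and 0 fell (12 and 0 adjusted over the list alone). Their median was 0.99 (camera adjusted p = 3.8e-05, and 0.13 with an estimated correlation). In the death receptor pathway, the deubiquitinase CYLD and the adaptor TRAF1 rose by 1.62 ± 0.22 and 2.56 ± 0.35, and LTA, a TNF family cytokine, by 4.14 ± 0.59. Without diluent replicate 2 or prexasertib replicate 2, the LTA value was 3.54 or 3.48. Of 25 pathway genes 13 rose and 0 fell (14 and 0 adjusted over the list alone). Their median was 0.40 (camera adjusted p = 0.00014, and 0.14 with an estimated correlation). TNFRSF1A, the main TNF receptor (chromosome 12, 6328757 to 6342114, minus strand), stood at 159 ± 11 CPM with diluent and 127 ± 27.9 CPM with prexasertib and had no call (-0.32 ± 0.18, adjusted p = 0.19). In the integrated stress and unfolded protein response list, DDIT3, a factor linked to stress-induced death, went from 10.1 ± 0.951 to 62.2 ± 18.2 CPM and PPP1R15A, a phosphatase subunit that restores translation, from 50.9 ± 6.82 to 416 ± 180 CPM. Of 27 genes 14 rose and 3 fell (14 and 4 adjusted over the list alone). Their median was 0.35 (camera adjusted p = 0.013, and 0.2 with an estimated correlation), or 0.23 without diluent replicate 2 and 0.22 without prexasertib replicate 1. The number that fell was 1 without diluent replicate 1 or 3 or prexasertib replicate 2.

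Cell cycle and DNA damage genes in U937 moved in both directions. CDKN1A, a CDK inhibitor and p53 target, went from 7.4 ± 0.714 to 83.9 ± 28.2 CPM, and GDF15, a stress cytokine, from 0.124 ± 0.0787 to 3.73 ± 1.02 CPM. AURKA, a mitotic kinase, went from 133 ± 5.18 to 343 ± 82.9 CPM and CDC20, an activator of the anaphase-promoting complex, from 217 ± 36.9 to 489 ± 117 CPM. CHEK1, the gene of the target of prexasertib (chromosome 11, 125625136 to 125676255), had no call (62.6 ± 2.38 and 71.1 ± 12.7 CPM, 0.18 ± 0.14, adjusted p = 0.31). CDK2, the S-phase kinase (chromosome 12, 55966769 to 55972784), fell from 60.7 ± 1.76 to 44.9 ± 5.14 CPM (-0.43 ± 0.12, adjusted p = 0.014), a call that ended without prexasertib replicate 2 (0.058). Of 29 p53 targets 10 rose, 0 fell (10 and 0 adjusted over the list alone) and 19, MDM2, BAX and FAS included, had no call. CDKN1A (3.50 ± 0.30), GDF15 (4.81 ± 0.41, and 5.51 without diluent replicate 1) and SESN2 (1.34 ± 0.20) rose. The list median was 0.28 (camera adjusted p = 0.0074, and 0.5 with an estimated correlation), and 1 fell without diluent replicate 2 or prexasertib replicate 1 or 3. Of 34 G2 and mitosis genes 21 rose and 0 fell (26 and 0 adjusted over the list alone), led by AURKA (1.37 ± 0.19), CDC20 (1.17 ± 0.21), UBE2C (1.13 ± 0.19) and NEK2 (1.05 ± 0.15). Their median was 0.43 (camera adjusted p = 2.3e-06, and 0.49 with an estimated correlation). The number that rose was 14 without prexasertib replicate 2, 12 without diluent replicate 3 and 11 without prexasertib replicate 1. The E2F and DNA replication list had no camera call (adjusted p = 0.086, median -0.17), and of its 37 genes 3 rose and 7 fell (2 and 5 adjusted over the list alone). It had a camera call toward lower values without diluent replicate 1 or 3 (0.01 and 0.041) or prexasertib replicate 2 or 3 (0.0042 and 0.033). Without diluent replicate 2 or prexasertib replicate 1, 4 fell and the median was -0.07, and without prexasertib replicate 2, 3 fell and it was -0.26. Without diluent replicate 1 or 3 or prexasertib replicate 2, 0 rose. POLA1 and TYMS, used in DNA and nucleotide synthesis, were among those that fell (-0.73 ± 0.13 and -0.62 ± 0.15). Of 24 homologous recombination and Fanconi genes 1 rose and 4 fell (1 and 4 adjusted over the list alone, and 7 fell without diluent replicate 1), with BRCA2 higher (1.05 ± 0.27), FANCC, FANCG and FANCI lower (-0.64, -0.45 and -0.47), and a median of -0.22 (camera adjusted p = 0.016, and 0.58 with an estimated correlation). Of 28 checkpoint and CDK regulators 6 rose and 3 fell (6 and 3 adjusted over the list alone), with WEE1 (0.97 ± 0.18) and CDC25B (0.57 ± 0.13) higher, and the list had no camera call (adjusted p = 0.68, median 0.13). Its median was 0.01 without diluent replicate 1, 0.08 without diluent replicate 3 and -0.04 without prexasertib replicate 2, and 5 or 1 fell without prexasertib replicate 1 or 2.

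Histone transcripts were among the larger changes in U937. HIST1H2AC went from 2.83 ± 1.25 to 72.9 ± 21.2 CPM and H1F0, a linker histone of resting cells, from 125 ± 12.5 to 495 ± 89 CPM. Of 19 histone genes 16 rose and 0 fell (18 and 0 adjusted over the list alone). Their median was 2.64 (camera adjusted p = 2.8e-10, and 0.2 with an estimated correlation), and 15 rose without prexasertib replicate 2. Histone genes have near-identical copies, so the split of reads between single members is uncertain. Interferon-stimulated genes included CXCL10, a T-cell chemokine, at 1.23 ± 0.549 CPM with diluent and 18.7 ± 8.43 CPM with prexasertib, and the RNA sensor IFIH1 at 31.4 ± 0.969 and 148 ± 88.1 CPM. Of 35 such genes 18 rose and 1 fell (21 and 1 adjusted over the list alone), the 1 that fell being BST2 (named after its values were seen), and the median was 1.14 (camera adjusted p = 6.3e-05, and 0.51 with an estimated correlation). Without prexasertib replicate 2 the count that rose was 13 with a median of 0.27, and IFIH1, IRF7 and IRF9 had log2 fold changes of 1.60, 1.48 and 1.18 in place of 2.23, 2.25 and 1.83.

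The genes with the largest calls in U937 were mostly low with diluent. PLA2G4C, a phospholipase, went from 0.162 ± 0.0614 to 26.3 ± 15.9 CPM, and DUSP8, a phosphatase of JNK and p38, from 0.43 ± 0.0022 to 21 ± 9.61 CPM. The log2 fold changes were 7.28 ± 0.62 for PLA2G4C, 5.91 ± 0.72 for the olfactory receptor gene OR2B6, 5.61 ± 0.45 for DUSP8, 5.36 ± 0.52 for TEX14 and 5.32 ± 0.46 for the immune receptor gene SLAMF7, with the largest adjusted p at 4.8e-05 (OR2B6). With prexasertib replicate 2 left out, they were 6.64 for PLA2G4C, 4.60 for TEX14 and 4.69 for SLAMF7. FRG2C and FRG2EP belong to a family of near-identical copies and their reads cannot be assigned with certainty. FRG2C had 2561 counts over the group against 2, a ratio of 1100 with a 95% counting interval of 305 to 9110, and FRG2EP had 2845 counts over the group against 1, a ratio of 2450 with a 95% counting interval of 439 to 96800. These intervals cover counting error only, and the 3 prexasertib libraries held 3.19, 32.1 and 3.54 CPM of FRG2C and 3.08, 36.5 and 3.61 CPM of FRG2EP. Decreases were smaller. SLC39A11, a zinc transporter, fell from 56.9 ± 6.3 to 25.5 ± 6.14 CPM, AFF2 from 315 ± 29.7 to 148 ± 42.9 CPM and TBC1D5, a Rab GTPase activator, from 157 ± 15.8 to 74.6 ± 28.3 CPM. The mTOR inhibitor gene DEPTOR fell by 1.43 on the log2 scale, and STXBP5L, BBS9, WFDC1 and TNIK changed by -1.23, -1.22, -1.13 and -1.08. Over all genes tested in U937, 3160 rose and 2209 fell under prexasertib, and 1882 and 62 of these changed at least 2-fold. Prexasertib replicate 2 stood apart from the other treated libraries: over 2678 genes, its change against diluent regressed on the mean change of the other pair with a slope of 1.35, against 0.888 and 0.778 for replicates 1 and 3. Without it the counts were 1803 and 881.

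In ML1, prexasertib raised most of the same transcription factors. JUN went from 10.3 ± 2.69 CPM with diluent to 1090 ± 294 CPM with prexasertib, FOS from 17.9 ± 2.24 to 344 ± 117 CPM and ATF3 from 4.62 ± 1.47 to 1060 ± 122 CPM. JUNB went from 41.8 ± 6.67 to 737 ± 193 CPM. They rose by 6.72 ± 0.47 (JUN), 4.27 ± 0.40 (FOS), 7.84 ± 0.56 (ATF3) and 4.14 ± 0.24 (JUNB), with adjusted p = 1.6e-08, 4.6e-07, 3.7e-08 and 3.8e-10. FOSB (6.86), FOSL1 (3.12), JUND (3.15), MAFF (4.0), MAFG (0.68), ATF5 (1.17) and BATF2 (4.44) also rose. FOSL2 (0.55 ± 0.27, adjusted p = 0.097) and ATF6 (0.22 ± 0.14, adjusted p = 0.21) had no call. In the list, 14 rose and 1 fell (15 and 1 adjusted over the list alone), JDP2 being the 1 that fell (named after its values were seen), and 2 fell without diluent replicate 1. Their median was 1.17 (camera adjusted p = 1.5e-06, and 0.19 with an estimated correlation).

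NF-kB targets in ML1 were among the largest changes. ICAM1, an adhesion molecule, went from 2.21 ± 0.285 to 184 ± 47.5 CPM, CXCL3, a chemokine with close paralogs, from 0.293 ± 0.139 to 60.3 ± 18.8 CPM, and BCL2A1, an antiapoptotic BCL2 relative, from 0.334 ± 0.0946 to 14.4 ± 3.6 CPM. Of 27 targets 26 rose and 1 fell (26 and 1 adjusted over the list alone), TNFAIP8 again being the 1 that fell. Their median was 5.45 (camera adjusted p = 2.3e-17, and 0.13 with an estimated correlation). Among other reported TNF regulators, CEBPB went from 19.8 ± 2.37 to 134 ± 15.2 CPM and NFKB2 from 15.1 ± 2.81 to 448 ± 25 CPM. In that list 16 rose and 2 fell (16 and 2 adjusted over the list alone). Their median was 0.78 (camera adjusted p = 0.00011, and 0.13 with an estimated correlation), and ELK1 and NFATC3 were the 2 that fell (named after their values were seen). Immediate early genes rose with DUSP5 (5.14 ± 0.30) and BTG2 (4.49 ± 0.21) among the smallest p-values. Of 24 immediate early genes 22 rose and 1 fell (22 and 1 adjusted over the list alone), MYC being the 1 that fell. Their median was 4.05 (camera adjusted p = 1.5e-13, and 0.13 with an estimated correlation). Of 16 MAPK feedback genes 12 rose and 1 fell (12 and 1 adjusted over the list alone). Their median was 1.86 (camera adjusted p = 2.2e-05, and 0.13 with an estimated correlation), and ETV4 was the 1 that fell (named after its values were seen). In the death receptor pathway TNFRSF10B, a TRAIL receptor, went from 95.6 ± 8.01 to 707 ± 164 CPM, TNFSF10, the gene of TRAIL, from 5.7 ± 0.306 to 70 ± 0.549 CPM and BIRC3 from 0.241 ± 0.117 to 57.4 ± 15.5 CPM. Of its 25 genes 21 rose and 1 fell (21 and 1 adjusted over the list alone), with FADD the 1 that fell (named after its values were seen, and with no call without diluent replicate 1 or 2 or prexasertib replicate 1) and a median of 0.96 (camera adjusted p = 2.3e-07, and 0.13 with an estimated correlation). TNFRSF1A had no call (0.00 ± 0.18, adjusted p = 1). Of 27 integrated stress genes 19 rose and 5 fell (21 and 5 adjusted over the list alone), with TRIB3 (3.49 ± 0.14) and PPP1R15A (4.83 ± 0.28) higher and a median of 1.17 (camera adjusted p = 3.7e-05, and 0.12 with an estimated correlation).

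Proliferation genes in ML1 went down together. CCNA2, the S and G2 cyclin, fell from 223 ± 6.66 to 43.1 ± 3.76 CPM and TOP2A, a topoisomerase used in chromosome separation, from 821 ± 24.3 to 191 ± 18 CPM. CHEK1 fell from 43.7 ± 1.67 to 19.2 ± 2 CPM and CDK2 from 177 ± 13.1 to 65 ± 8.9 CPM (-1.18 ± 0.14 and -1.44 ± 0.13, adjusted p = 1.6e-06 and 4.6e-08). Of 37 E2F and DNA replication genes 0 rose and 37 fell (0 and 37 adjusted over the list alone). Their median was -1.64 (camera adjusted p = 2.2e-18, and 0.2 with an estimated correlation). Of 34 G2 and mitosis genes 0 rose and 34 fell (0 and 34 adjusted over the list alone). Their median was -1.41 (camera adjusted p = 2.3e-17, and 0.2 with an estimated correlation). Homologous recombination and Fanconi genes included FANCI (-1.87 ± 0.12), and of 24 in the list 0 rose and 21 fell (0 and 22 adjusted over the list alone). Their median was -1.50 (camera adjusted p = 1.7e-12, and 0.13 with an estimated correlation). Of 28 checkpoint and CDK regulators 5 rose and 17 fell (5 and 18 adjusted over the list alone, and 3 rose without prexasertib replicate 2), with CDK1 (-2.0 ± 0.15) and TIMELESS (-1.80 ± 0.11) lower, CDKN1A higher (4.95 ± 0.32) and a median of -0.80 (camera adjusted p = 0.00026, and 0.25 with an estimated correlation).

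The p53 targets in ML1 moved the other way. GDF15 went from 0.272 ± 0.12 to 41.8 ± 9.77 CPM, PLK3, a stress kinase, from 6.82 ± 0.342 to 49.9 ± 4.84 CPM and CDKN1A from 61.3 ± 18.9 to 1890 ± 49.5 CPM. Of 29 p53 targets 28 rose and 0 fell (28 and 0 adjusted over the list alone). Their median was 2.48 (camera adjusted p = 2.3e-16, and 0.12 with an estimated correlation). Interferon-stimulated genes rose too. IFI27 went from 0.543 ± 0.125 to 731 ± 107 CPM, IFITM1, which blocks virus entry, from 0.3 ± 0.139 to 88.6 ± 4.96 CPM and USP18, which removes ISG15 from proteins, from 9.58 ± 0.897 to 338 ± 48.9 CPM. Of 35 such genes 35 rose and 0 fell (35 and 0 adjusted over the list alone). Their median was 5.02 (camera adjusted p = 4.5e-24, and 0.13 with an estimated correlation). Of 19 histone genes 15 rose and 1 fell (16 and 2 adjusted over the list alone), H2AFZ being the 1 that fell (named after its values were seen, and 2 fell without prexasertib replicate 2), with H1F0 higher (4.30 ± 0.26) and a median of 2.33 (camera adjusted p = 2.1e-05, and 0.38 with an estimated correlation). The largest increases in ML1 were those of ARC, a synaptic regulator (10.56 ± 0.68), IFI27 (10.37 ± 0.25), IFI44L (10.28 ± 0.75), EPSTI1 (10.17 ± 0.36), the ubiquitin ligase gene NEURL3 (10.10 ± 0.54) and IFI44 (10.04 ± 1.13), with the largest adjusted p at 1.1e-05 (IFI44). Without diluent replicate 2 the IFI44L value was 10.94, and without diluent replicate 3 the NEURL3 value was 10.99. CCL3L1, a chemokine gene whose copies share reads with CCL3 and whose level is therefore uncertain, had 3144 counts over the prexasertib group and 0 with diluent, at least 1240-fold higher (floor of 3 counts over the group). COL5A3, a collagen gene, had 2446 counts over the group against 2, a ratio of 1440 with a 95% counting interval of 399 to 11900. The largest decreases were those of TNR (-4.88 ± 0.61, and -5.78 without prexasertib replicate 3), TERT, the telomerase subunit (-4.30 ± 0.31), FAM135B (-3.15 ± 0.23) and BCL2, the antiapoptotic gene (-3.14 ± 0.17). CDCA7L, F13A1, NREP and ITPRIPL1 changed by -2.86, -2.81, -2.71 and -2.64. Over all genes tested in ML1, 4370 rose and 4049 fell, and 2666 and 1379 of these changed at least 2-fold.

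Changes in the 2 lines overlapped. Of the 17243 genes tested, 1701 rose in both lines (801 for independent lists), among them TNF, JUN, FOS, ATF3 and CDKN1A, and 1291 fell in both (519 for independent lists), among them CDK2, TYMS and POLA1. Only 175 rose in U937 and fell in ML1 (742 for independent lists), and 155 did the opposite (560). The odds ratios for a shared direction were 4.99 for increases and 6.26 for decreases, and log2 fold changes correlated across genes with Pearson's r of 0.458 and Spearman's rho of 0.461. Genes are not independent replicates, and no library is shared by the 2 comparisons. Without U937 prexasertib replicate 2, 1121 genes rose in both and 594 fell in both.

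The difference between the lines was tested gene by gene. IFI27 stood at 0.761 ± 0.261 and 0.821 ± 0.186 CPM in U937 with diluent and prexasertib, against the rise to 731 ± 107 CPM in ML1, a difference of -10.26 ± 0.34 (adjusted p = 1.3e-12). EPSTI1, GBP1, ARC and CYP4F3 had the same direction (-10.46 ± 0.95, -9.30 ± 1.13, -8.97 ± 1.42 and -8.60 ± 0.72), with ARC at -8.17 without U937 diluent replicate 2 and -10.64 without prexasertib replicate 2. The U937 diluent and prexasertib groups held 21 and 20 counts of EPSTI1, 25 and 19 of GBP1, 16 and 56 of ARC and 55 and 44 of CYP4F3. SLC12A7, a potassium chloride cotransporter, went from 36.9 ± 7.99 to 21 ± 4.23 CPM in ML1 and from 0.0764 ± 0.036 to 7.23 ± 5.66 CPM in U937 (7.26 ± 0.99, adjusted p = 6.7e-05, and 6.36 without prexasertib replicate 2). ZNF615, ZC3HAV1L, ZNF521 and TRIQK passed the same test with fitted values of 6.72, 6.60, 5.94 and 4.76, but their U937 diluent groups held 0, 0, 1 and 0 counts, so these values depend on the prior count and are no fold. The TRIQK call ended without any of the 3 U937 diluent replicates (adjusted p = 0.075, 0.063 and 0.06) or prexasertib replicate 2 (0.14), and ZNF521 was 7.91 without diluent replicate 1 and 4.75 without prexasertib replicate 2. Among cell cycle genes, the effect on CHEK1 and CDK2 was higher in U937 by 1.37 ± 0.19 and 1.01 ± 0.17 (adjusted p = 4.5e-05 and 0.00034). JUN, JUNB, FOSB and ATF3 responded less in U937 (-2.38 ± 0.53, -2.61 ± 0.31, -4.0 ± 0.45 and -2.91 ± 0.62, with ATF3 at -3.59 without prexasertib replicate 2), and FOS had no call (-0.63 ± 0.51, adjusted p = 0.41). Over all genes, the change was higher in U937 for 2140 and lower for 2124, of which 1180 and 1398 differed by at least 1 on the log2 scale.

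**Figure D2:**
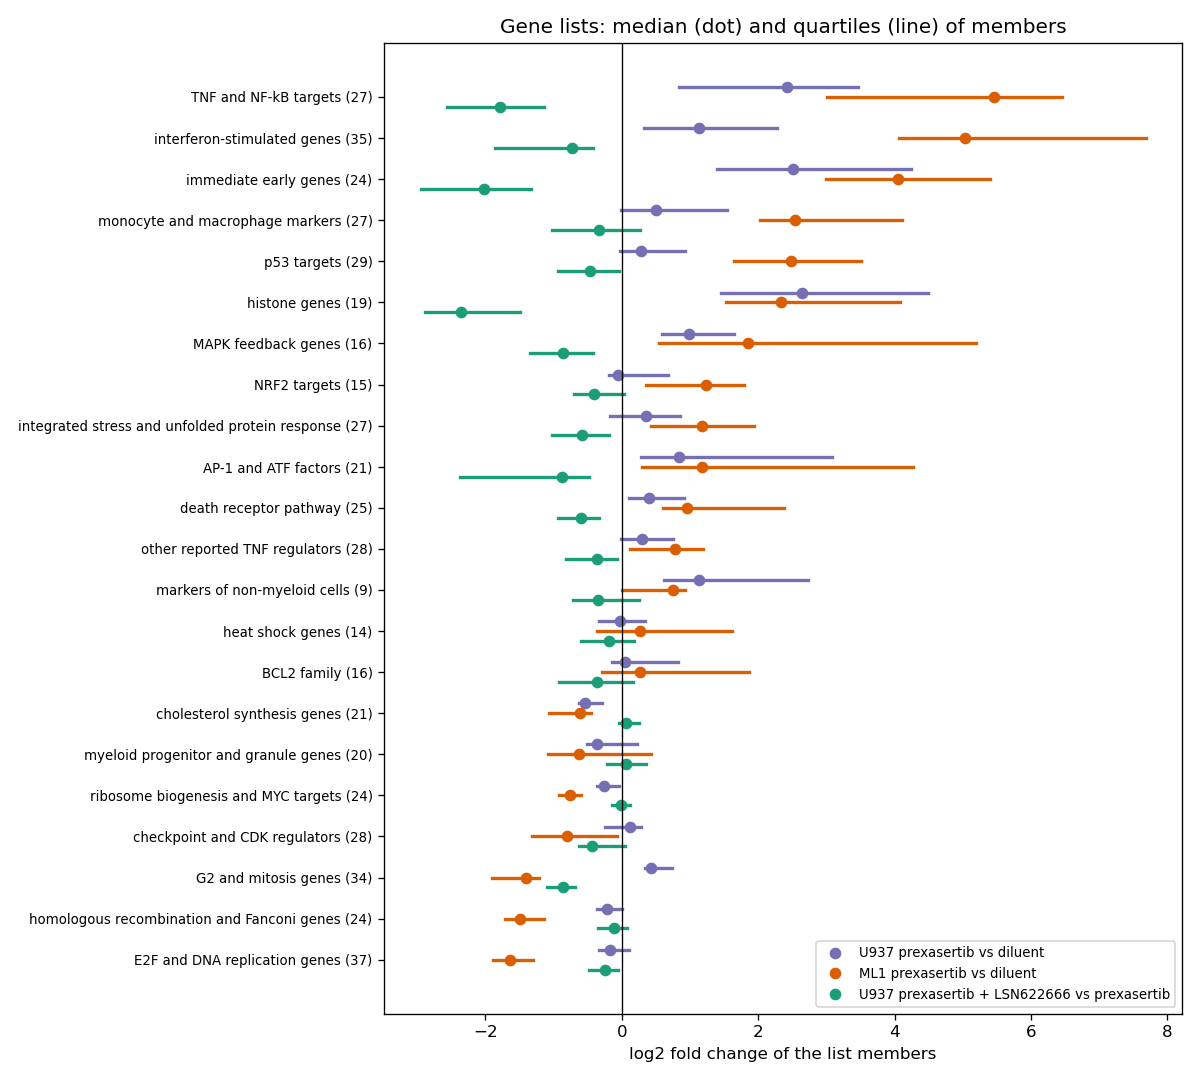
Median (dot) and quartiles (line) of the log2 fold changes of each list's tested members in 3 comparisons; the number of members is in parentheses. G2 and mitosis genes had medians of 0.43 in U937, -1.41 in ML1 and -0.86 on adding LSN622666.

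Adding LSN622666 to prexasertib in U937 tested whether this compound changes the induced genes. JUN went from 558 ± 268 CPM with prexasertib to 38.9 ± 22.3 CPM with the combination, FOS from 51.5 ± 25.4 to 9.97 ± 4.53 CPM, ATF3 from 185 ± 117 to 15 ± 9.78 CPM and JUND from 174 ± 34.1 to 47.4 ± 5.35 CPM. The log2 fold changes were -3.84 ± 0.41 (JUN), -2.37 ± 0.37 (FOS), -3.63 ± 0.46 (ATF3) and -1.88 ± 0.15 (JUND), with adjusted p = 2.2e-05, 4e-04, 9.5e-05 and 1.6e-06. FOSB (-1.68), FOSL2 (-1.54), JUNB (-1.59), MAFF (-2.49), MAFG (-0.60), ATF6 (-0.88) and BATF2 (-2.38) fell too. Without prexasertib replicate 2, ATF3 changed by -2.98, and without combination replicate 2 ATF3 changed by -4.31. Of 21 AP-1 and ATF factors 0 rose and 16 fell (0 and 17 adjusted over the list alone). Their median was -0.88 (camera adjusted p = 2.5e-08, and 0.13 with an estimated correlation). With prexasertib replicate 2 left out, 14 fell.

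Other lists raised in U937 by prexasertib were lower in the combination, except the monocyte and non-myeloid marker lists, which had no camera call there (adjusted p = 0.29 and 0.72). CXCL8 went from 202 ± 66.8 to 18 ± 9.58 CPM, DUSP1 from 51.7 ± 15.7 to 5.84 ± 3.06 CPM and EGR1 from 58.5 ± 38.5 to 5.53 ± 2.45 CPM, and without prexasertib replicate 1 the log2 fold change of EGR1 was -2.75 in place of -3.41. Of 27 TNF and NF-kB targets 0 rose and 23 fell (0 and 24 adjusted over the list alone). Their median was -1.78 (camera adjusted p = 9.5e-12, and 0.13 with an estimated correlation). Of 24 immediate early genes 0 rose and 22 fell (0 and 23 adjusted over the list alone). Their median was -2.02 (camera adjusted p = 2.3e-13, and 0.13 with an estimated correlation). Of 16 MAPK feedback genes 0 rose and 12 fell (0 and 13 adjusted over the list alone). Their median was -0.87 (camera adjusted p = 3.7e-05, and 0.13 with an estimated correlation). Of 28 other TNF regulators 1 rose and 14 fell (1 and 15 adjusted over the list alone), IRF8 being the 1 that rose. Their median was -0.37 (camera adjusted p = 0.00035, and 0.13 with an estimated correlation). In the death receptor pathway 1 rose and 15 fell (1 and 16 adjusted over the list alone) of 25, RIPK3 being the 1 that rose (named after its values were seen), with BIRC3 and CYLD lower (-2.40 ± 0.31 and -1.54 ± 0.21) and a median of -0.60 (camera adjusted p = 3.9e-05, and 0.13 with an estimated correlation). TNFRSF1A had no call (0.08 ± 0.18, adjusted p = 0.78). Of 27 integrated stress genes 0 rose and 16 fell (0 and 17 adjusted over the list alone), with DDIT3 at 62.2 ± 18.2 and 10.1 ± 1.99 CPM and a median of -0.58 (camera adjusted p = 6.7e-07, and 0.11 with an estimated correlation). Without prexasertib replicate 2, 19 TNF and NF-kB targets, 21 immediate early genes, 9 death receptor genes and 10 other TNF regulators fell, and 9 of the latter fell without combination replicate 3. The RIPK3 and IRF8 calls ended without prexasertib replicate 2 or 3 or combination replicate 1 or 3.

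Part of the cell cycle genes were lower in the combination than with prexasertib alone. AURKA went from 343 ± 82.9 to 113 ± 24.7 CPM, KIF20A, a mitotic kinesin, from 200 ± 43.4 to 73.4 ± 19.2 CPM and CDKN1A from 83.9 ± 28.2 to 11 ± 4.81 CPM. CHEK1 fell from 71.1 ± 12.7 to 45.5 ± 7.16 CPM (-0.64 ± 0.14, adjusted p = 0.0022), and CDK2 had no call (0.10 ± 0.12, adjusted p = 0.57). Of 34 G2 and mitosis genes 0 rose and 34 fell (0 and 34 adjusted over the list alone). Their median was -0.86 (camera adjusted p = 1.2e-16, and 0.2 with an estimated correlation). Of 19 histone genes 0 rose and 19 fell (0 and 19 adjusted over the list alone). Their median was -2.35 (camera adjusted p = 2.1e-11, and 0.19 with an estimated correlation). Of 29 p53 targets 0 rose and 11 fell (0 and 12 adjusted over the list alone). Their median was -0.47 (camera adjusted p = 0.00052, and 0.36 with an estimated correlation). Of 37 E2F and replication genes 0 rose and 10 fell (0 and 10 adjusted over the list alone), with E2F2 and E2F8 lower (-1.61 ± 0.25 and -0.96 ± 0.14) and a median of -0.25 (camera adjusted p = 0.0074, and 0.74 with an estimated correlation). That camera call ended without prexasertib replicate 3 (0.1) or combination replicate 1 (0.44, median -0.08), and the median was -0.14 without prexasertib replicate 2 and -0.41 without combination replicate 2. The number that fell was 4 without prexasertib replicate 2 and 5 without combination replicate 1 or 3, and 1 rose without prexasertib replicate 3. Of 28 checkpoint and CDK regulators 0 rose and 14 fell (0 and 14 adjusted over the list alone, and 1 rose without prexasertib replicate 1, 2 or 3), with WEE1 lower (-1.35 ± 0.19) and a median of -0.44 (camera adjusted p = 0.0038, and 0.37 with an estimated correlation). The homologous recombination list had no camera call (adjusted p = 0.46, median -0.12), and in it 1 rose and 4 fell (1 and 3 adjusted over the list alone). Its median was 0.01 without combination replicate 1 and -0.20 without combination replicate 2, 2 rose without prexasertib replicate 1 or 3, and 1, 2 and 1 fell without prexasertib replicate 2 and combination replicates 1 and 3. Of 35 interferon-stimulated genes 0 rose and 17 fell (0 and 20 adjusted over the list alone), with CXCL10 at 18.7 ± 8.43 and 1.7 ± 0.968 CPM and a median of -0.74 (camera adjusted p = 0.00061, and 0.58 with an estimated correlation), and 9 fell without prexasertib replicate 2 (median -0.30), 10 without combination replicate 1 and 8 without combination replicate 3.

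The genes with the largest decreases on adding LSN622666 were among those raised by prexasertib. DUSP8 went from 21 ± 9.61 to 1.31 ± 0.683 CPM, CREB5, a bZIP factor, from 25 ± 11 to 1.47 ± 0.814 CPM and NEU4, a sialidase, from 18.7 ± 4.15 to 1.47 ± 0.394 CPM (-4.0 ± 0.40, -4.09 ± 0.45 and -3.67 ± 0.28). SLAMF7 and PLA2G4C changed by -3.98 ± 0.42 and -3.96 ± 0.48, and by -3.37 and -3.34 without prexasertib replicate 2, with PLA2G4C at -4.76 without combination replicate 2. FRG2C and FRG2EP, with reads shared between copies, also passed (-4.74 ± 1.28 and -4.45 ± 1.22), and both calls ended without prexasertib replicate 2 (adjusted p = 0.066 and 0.068) and in a fit to the 2 groups alone (0.092 and 0.078). FRG2EP also lost its call with no low-count filter (0.052) and without combination replicate 1 or 3 (0.07 and 0.064). Without combination replicate 2, FRG2C and FRG2EP were at -10.54 and -6.86, and FRG2C at -4.15 without combination replicate 3 (106 counts over that group). Genes that rose included DNHD1, a dynein heavy chain relative, from 35.9 ± 6.4 to 139 ± 54.1 CPM, and MAPK8IP2, a JNK scaffold, from 4.27 ± 1.15 to 16.4 ± 5.11 CPM. SCART1 (2.49 ± 0.27), SPON2 (2.39 ± 0.35), ZDHHC11, which has a near-identical paralog and is uncertain (2.24 ± 0.38), MFSD7 (1.89 ± 0.34) and MYOF (1.97 ± 0.38, and 2.58 without prexasertib replicate 1) rose as well. Over all genes, 2048 rose and 2947 fell, and 594 and 1253 of these changed at least 2-fold. Under upper-quartile factors the counts were 2633 and 2560. With prexasertib replicate 2 left out, they were 1105 and 1794, and without combination replicate 1 or 3 the number that rose was 1331 or 1362. Replicate numbers paired these 2 groups (correlations of 0.409, 0.37 and 0.384), and with replicate as a block 3239 genes rose.

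Reversal of prexasertib changes by LSN622666 was counted over genes. Of 3160 genes raised by prexasertib in U937, JUN, FOS, ATF3 and TNF among them, 2043 (64.7%) fell in the combination (540 for independent lists) and 25 rose further. Of 2209 genes lowered by prexasertib, SLC39A11, AFF2 and TBC1D5 among them, 724 (32.8%) rose in the combination (262 for independent lists) and 6 fell further. Of these 5369 genes, 743 (13.8%) also changed against diluent in the combination (308 for independent lists, same sign). This number was 245 and 289 without diluent replicates 2 and 3 and 272 and 432 without combination replicates 1 and 2. Over 1944 genes changed at least 2-fold by prexasertib the median share of the change undone was 62.3% (quartiles 38.9 to 85.1%). These comparisons share the prexasertib libraries. The covariance of the log2 fold changes was -0.906, against -0.0813 ± 0.00542 (SD) in 20 simulations with no effect, a difference of -0.825. At most 1 gene was called changed there by edgeR's quasi-likelihood test and 0 reversed, too few to judge reversal. Prexasertib and combination changes against the shared diluent libraries had a covariance of 0.675, against 0.0845 simulated, a difference of 0.591. A group of 3 libraries cannot be split into parts of at least 2, so the shared libraries may add to the excess over independent lists and the share undone. Without prexasertib replicate 2, 1067 of 1803 raised genes fell back and 162 of 881 lowered genes rose back. Lowered genes that rose back numbered 1089 without prexasertib replicate 3, 373 without combination replicate 3 and 1695 with replicate as a block.

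**Figure D3:**
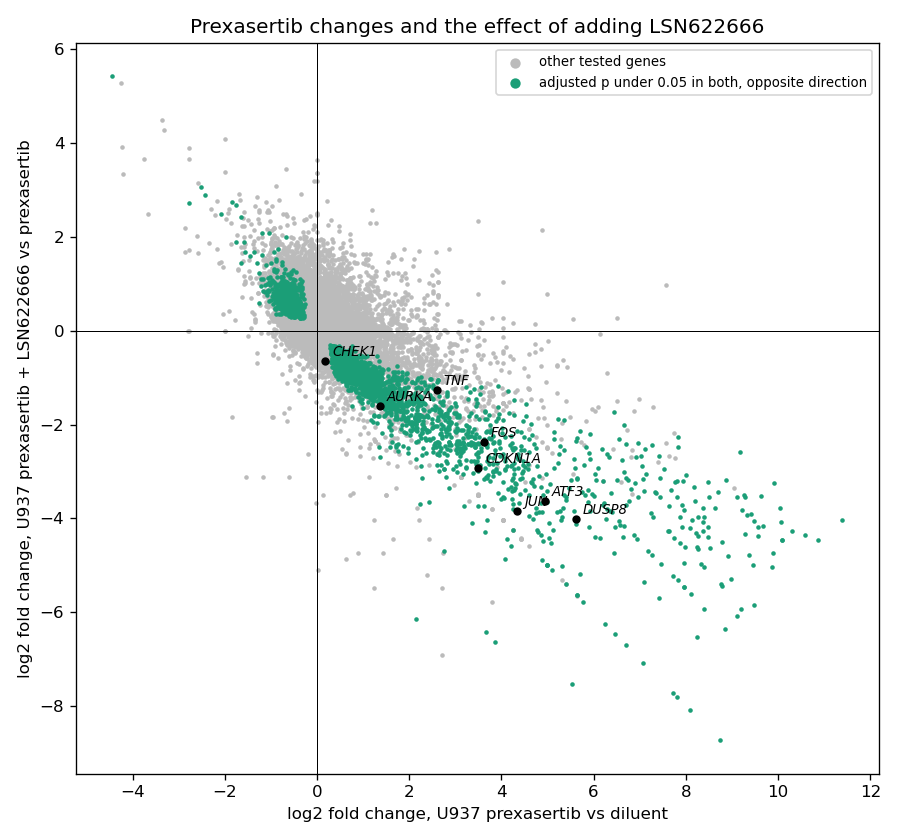
Log2 fold change of each tested gene under prexasertib against diluent in U937 (horizontal) and on adding LSN622666 to prexasertib (vertical); green marks genes called in both with opposite directions. JUN lies at 4.35 and -3.84, TNF at 2.61 and -1.27.

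The combination was also compared with diluent in U937. COL7A1, a collagen gene, went from 13.3 ± 1.21 CPM with diluent to 66.3 ± 19.3 CPM with the combination, DNHD1 from 28.8 ± 6.81 to 139 ± 54.1 CPM and VWA7 from 2.56 ± 0.241 to 11.9 ± 1.86 CPM. PRTN3, a granule protease of myeloid cells, fell from 333 ± 27.3 to 155 ± 30.1 CPM, and CCNA2 from 165 ± 11.2 to 93.8 ± 16.6 CPM. The log2 fold changes were 2.31 ± 0.25 (COL7A1), 2.27 ± 0.24 (DNHD1), 2.22 ± 0.22 (VWA7), -1.11 ± 0.20 (PRTN3) and -0.82 ± 0.12 (CCNA2), with adjusted p = 7.3e-05, 7.3e-05, 4.7e-05, 0.0034 and 0.00081. MYH3 (2.30) and OVGP1 (2.25) rose, and DNHD1, VWA7 and ADAM11 had no call under prexasertib alone. TNXB (3.14, and 2.47 without combination replicate 1), ADAM11 (2.45, and 1.86 without combination replicate 1) and HIST1H2AC (2.30, and 1.43 without combination replicate 2) rose too, and TNXB shares reads with a pseudogene copy. The kinetochore gene SPC25, MRPL1, PTAFR, TMBIM4, COMMD10 and CTDSPL2 changed by -0.95, -1.10, -0.98, -0.92, -0.90 and -0.87. ANXA2R fell by 0.98 on the log2 scale (adjusted p = 0.038), a call that ended without diluent replicate 1 (adjusted p = 0.19) and without each of combination replicates 1, 2 and 3 (0.075, 0.11 and 0.07). CHEK1 stood at 62.6 ± 2.38 and 45.5 ± 7.16 CPM (-0.46 ± 0.14, adjusted p = 0.039), a call that ended without diluent replicate 1, 2 or 3 (0.06, 0.089 and 0.058), without combination replicate 1 or 3 (0.14 and 0.086), and under upper-quartile factors (0.087). CDK2 (-0.33 ± 0.12, adjusted p = 0.086) and TNFRSF1A (-0.24 ± 0.18, 0.4) had no call.

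Of the AP-1 factors, JUN and ATF3 had no call in the combination against diluent (0.51 ± 0.37 and 1.31 ± 0.44, adjusted p = 0.39 and 0.068). In that list 2 rose and 1 fell (2 and 1 adjusted over the list alone) of 21, with no camera call (adjusted p = 0.57, median 0.10). Its median was 0.17, -0.06 and -0.07 without diluent replicates 2 and 3 and combination replicate 2, and 0 rose without these or combination replicate 1. NFKB2 and TNFAIP3 were higher than with diluent (1.08 ± 0.21 and 1.23 ± 0.29), the latter losing its call without diluent replicate 3 (0.058) or combination replicate 2 (0.054). Of 27 TNF and NF-kB targets 7 rose and 0 fell (11 and 2 adjusted over the list alone). Their median was 0.80 (camera adjusted p = 0.0077, and 0.58 with an estimated correlation), and without combination replicate 2 it was 0.33 with no camera call (0.16). The number that rose was 4, 2 and 1 without diluent replicates 1, 2 and 3 and 2 without combination replicate 1 or 2. Of 24 immediate early genes 6 rose and 0 fell (9 and 0 adjusted over the list alone). Their median was 0.52 (camera adjusted p = 0.0057, and 0.58 with an estimated correlation), with no camera call without combination replicate 2 (0.12). The number that rose was 3, 1 and 0 without diluent replicates 1, 2 and 3, and 2 and 0 without combination replicates 1 and 2. Replication and mitosis lists were lower than with diluent. PCNA, the replication clamp, changed by -0.74 ± 0.16. Of 37 E2F and replication genes 0 rose and 8 fell (0 and 16 adjusted over the list alone). Their median was -0.36 (camera adjusted p = 2.6e-09, and 0.39 with an estimated correlation), and 2 and 4 fell without diluent replicates 2 and 3, and 1, 16 and 4 without combination replicates 1, 2 and 3. Of 34 G2 and mitosis genes 0 rose and 8 fell (0 and 19 adjusted over the list alone). Their median was -0.37 (camera adjusted p = 5.1e-09, and 0.38 with an estimated correlation), and 5, 3 and 4 fell without diluent replicates 1, 2 and 3, and 1, 16 and 2 without combination replicates 1, 2 and 3. The p53 target and death receptor lists had no camera call (adjusted p = 0.67 and 0.91). For the death receptor list the median (-0.02) and the mean (0.19) differed in sign, as they did for the p53 targets (-0.02 and 0.02) and the other TNF regulators (-0.06 and 0.03), and each of these medians changed sign with the scaling factors. Over all genes, 1186 rose and 709 fell, and 682 and 14 of these changed at least 2-fold. Under upper-quartile factors the split was 1528 higher and 236 lower. The counts of genes that rose and fell were 463 and 247 without diluent replicate 2, 557 and 295 without diluent replicate 3, and 425 and 179 without combination replicate 1, and 391 fell without combination replicate 3.

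With diluent alone, the lines differed widely. SRPX was found in U937 and not in ML1 (1854 counts against 0, at least 716-fold higher), and RNF165, a ubiquitin ligase gene, had 2554 counts over the group against 2, a ratio of 1480 with a 95% counting interval of 409 to 12200. CD276, an immune checkpoint molecule, stood at 25.7 ± 2.67 CPM in U937 and 0.0254 ± 0.00938 CPM in ML1, HDGFRP3 at 21.2 ± 1.41 and 0.0192 ± 0.0174 CPM, and IMPACT, a regulator of translation, at 23.4 ± 3.96 and 0.0296 ± 0.0513 CPM. ZC3HAV1L (4632 counts against 0, at least 1330-fold), TRIQK (2607 counts against 0, at least 750-fold), the pseudogene CYP4F29P (2296 counts against 0, at least 661-fold) and ZNF615 (2183 counts against 0, at least 628-fold) were higher in ML1, where a floor of 3 counts over the U937 group was used. ZNF521, a zinc finger gene, was also higher in ML1, with 4454 counts over the group against 1, a ratio of 3850 with a 95% counting interval of 690 to 152000. CHEK1 was higher in U937 (0.52 ± 0.14, adjusted p = 0.003) and CDK2 lower (-1.54 ± 0.13, adjusted p = 7.2e-09), and TNFRSF1A had no call (0.30 ± 0.18, 0.18). The fitted log2 fold change of IMPACT, 9.74, was 9.01 without ML1 diluent replicate 2 and 13.57 without replicate 3. Over all genes, 5510 were higher in U937 and 5076 lower, and 3382 and 2575 of these differed at least 2-fold.

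Some named genes share exonic positions with another annotated gene in GENCODE v29 on GRCh38. The kit does not mark strand and the strand setting of the counting is not given, so their reads cannot be told apart from those of the neighbour. CDK2 exons overlap those of PMEL on the opposite strand, and CHEK1 exons overlap those of STT3A. The same holds for ANXA2R, ATF5, CCL3L1, CCNA2, CDCA7L, CDKN1A, CEBPB, COL5A3, COL7A1, COMMD10, CTDSPL2, CYLD, DDIT3, DEPTOR, DNHD1, E2F8, ETV4, FADD, FANCC, FANCI, H2AFZ, ICAM1, IER3, IFITM1, IRF9, JDP2, JUNB, KIF20A, MAFG, NEU4, NFATC3, NREP, PHLDA1, PLA2G4C, PLK3, RIPK3, TBC1D5, TEX14, TMBIM4, TNFAIP3, TNFRSF10B, TNR, TNXB, TRIQK, TYMS, WEE1 and ZDHHC11, whose values are uncertain to that extent. HDGFRP3 and MFSD7 had no match in this annotation.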

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

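In this part, the tests of scaling and of a weaker response and the bound for the count of other splits were set after their results were seen, as was leaving out libraries for the lists. The recomputation on thinned counts was set before. Each result here was singled out because the prexasertib effect in U937 differed from that in ML1 in a direct test of the difference, given as U937 minus ML1 on the log2 scale. The test called 2140 genes with a difference above 0 and 2124 with one below 0. Among named genes the differences were 7.26 for SLC12A7, -10.46 for EPSTI1, -10.26 for IFI27, -9.30 for GBP1, -8.97 for ARC and -8.60 for CYP4F3. For ZNF615, ZC3HAV1L, ZNF521 and TRIQK, at 0 or 1 count with diluent in U937, the fitted values 6.72, 6.60, 5.94 and 4.76 are no fold. The differences were -3.05 for TNF, 1.37 for CHEK1 and 1.01 for CDK2. Among AP-1 and ATF factors they were -4.0 for FOSB, -2.53 for FOSL1, -2.38 for JUN, -2.61 for JUNB, -1.46 for JUND and -2.91 for ATF3.

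ATF6 differed by 0.62 (adjusted p = 0.031). That call ended without ML1 diluent replicate 1, 2 or 3 (adjusted p = 0.05, 0.056 and 0.062), ML1 prexasertib replicate 2 or 3 (0.05 and 0.058), U937 diluent replicate 2 or 3 (0.077 and 0.089) or U937 prexasertib replicate 2 (0.088). Without U937 prexasertib replicate 2, ATF3 differed by -3.59.

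Lists whose difference passed camera with the preset correlation are given by their median difference, and none passed with an estimated correlation. Medians below 0 were found for AP-1 and ATF factors (-0.64, adjusted p = 0.43 with an estimated correlation), the death receptor pathway (-0.46, 0.16), immediate early genes (-1.36, 0.31), integrated stress genes (-0.66, 0.13) and interferon-stimulated genes (-3.59, 0.13). They were also below 0 for MAPK feedback genes (-0.99, 0.28), monocyte markers (-2.05, 0.11), NRF2 targets (-0.72, 0.28), other TNF regulators (-0.33, 0.13), p53 targets (-1.95, 0.11) and TNF and NF-kB targets (-2.52, 0.13). Medians above 0 were found for checkpoint and CDK regulators (0.98, 0.19), E2F and replication genes (1.5, 0.2), G2 and mitosis genes (2.05, 0.13), homologous recombination genes (1.25, 0.13) and ribosome and MYC targets (0.56, 0.62). Without U937 prexasertib replicate 2 the median was -1.06 for AP-1 and ATF factors and -0.50 for other TNF regulators, and without ML1 diluent replicate 1 it was -0.53 for other TNF regulators and -1.10 for NRF2 targets.

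The number of genes that differ between the lines, 4264, was set against other splits of the libraries. Of 100 drawn from 200 possible splits, 9, the real one included, called as many genes, and the highest other split called 9285. All 8 of those other splits exchange 2 or 3 U937 libraries between diluent and prexasertib and no ML1 library, which turns the sign of the U937 effect, in full or in part, and keeps the ML1 effect. They are therefore no reference for chance, and the splits do not decide whether chance can be excluded. Of the other splits, 10 exchange U937 libraries in that way, and the highest split outside these 10 called 3718. The counts point to a structure of the samples, namely the large treatment effects in both lines.

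Of 34 G2 and mitosis genes, 21 were called higher in U937 (median 0.43, quartiles 0.35 to 0.73) and 34 lower in ML1 (median -1.41). In U937 the number was 14 without prexasertib replicate 2, 12 without diluent replicate 3 and 11 without prexasertib replicate 1, and with an estimated correlation camera gave adjusted p = 0.49 and 0.2 in U937 and ML1. The choice of scaling factors is argued against as the source, since the smaller U937 median under the other scalings was 0.42, and the median on thinned counts was 0.41, which argues against depth. A weaker form of the ML1 fall needs U937 values between -1.41 and 0, which the 21 genes called higher argue against, although no value apart from the pattern tests it. A biological difference between the lines stays open, which no group in the design isolates and which was not tested. A change in the share of cells in each cycle phase and a change of expression within cells cannot be separated in counts from whole cultures.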

How the results depend on the processing

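Leaving out the 2 treated U937 libraries numbered 2 together was chosen after seeing the data, as were the overlap between lines and the gene lists with a library left out. Of 642 results for named genes, recomputed in 10407 alternative values, 9811 kept their side of the threshold, 448 lost the call and 148 gained one. Among values with a call in the main or the alternative fit, 0 changed direction. Direction was not compared where neither fit had a call. With a threshold of 1 on the absolute log2 fold change, the counts higher and lower were 1882 and 62 (U937 prexasertib), 2666 and 1379 (ML1), 594 and 1253 (combination against prexasertib), 682 and 14 (combination against diluent), 1180 and 1398 (difference between lines) and 3382 and 2575 (diluent), and 1161 and 40 genes reversed downward and upward, since fewer genes can pass. In U937, genes lower with prexasertib numbered 1449 under the stricter filter, which tests fewer genes, and 1008 in a fit to the groups compared, which has fewer samples. Genes lower in the combination than with diluent numbered 1395 in DESeq2, 236 under upper-quartile factors, 273 under the stricter filter and 218 in a fit to U937 alone, and the cause was not tested. With no low-count filter, TNF lost its call in the combination against prexasertib (-1.27, adjusted p = 0.065) and diluent (1.33, 0.12), where more genes enter the adjustment. With both libraries numbered 2 left out, the counts were 1778 and 774 (U937 prexasertib), 1099 and 1720 (combination against prexasertib), 1121 and 521 (shared with ML1) and 1054 and 158 (reversed), and TNF in the combination against diluent was at 0.88 (adjusted p = 0.075). Of 132 list tests camera called 80 with the preset and 0 with an estimated correlation (34 at an unadjusted p under 0.05), and fry called 85. Genes changed by prexasertib and still changed against diluent in the combination numbered 743, and 1281 in DESeq2, 434 under the stricter filter, 345 with the threshold of 1 and 413 with both libraries numbered 2 left out.

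With replicate as a block, 3239 genes were higher in the combination than with prexasertib, where numbers pair samples. In the other comparisons, and for reversal, which also uses diluent, pairing stays open. There the block gave 1695 reversed upward and 4375 in all (2767 without it), 3682 lower genes with prexasertib in U937, 2218 higher and 2065 lower in the combination against diluent, 2210 lower in both lines and 1892 genes still changed against diluent. With the block 83 list tests passed. Only replicate 2 of U937 diluent and prexasertib correlated best with another number.

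Leaving out 1 library at a time gave ranges. For U937 prexasertib the counts were 1803 to 3565 higher and 881 to 2727 lower, for the combination against prexasertib 1105 to 2108 and 1794 to 3057, and for the combination against diluent 425 to 1061 and 179 to 714. For ML1 they were 3775 to 4023 and 3531 to 3933, for the difference between lines 1585 to 2077 and 1803 to 2248, and for diluent 5085 to 5240 and 4602 to 4845. Shared changes ran from 1121 to 1847 higher and 594 to 1614 lower, and reversed genes from 1067 to 2340 and 162 to 1089. The log2 fold change of TNF ran from 2.17 to 2.85 in U937 and 5.37 to 6.01 in ML1, from -1.70 to -0.86 in the combination against prexasertib, from 0.90 to 1.60 against diluent, from -3.49 to -2.75 for the difference and from -0.82 to -0.17 between lines with diluent. Depth limits genes near the floor: 1293 of the 3160 genes higher in U937 (40.9%) had a diluent mean under 1 CPM.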

Other observations

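In this part, the comparison of the real split of 3 against 3 libraries with the others, the test of depth for the detected genes and leaving out libraries for lists and for genes of the combination were set after their results were seen. The tests of background, of GC content and of depth for the genes higher in the combination were set before theirs. Several lists were outside the question of TNF regulation. Monocyte and macrophage markers in ML1 included CYBB, the oxidase subunit, at 2.07 ± 0.555 CPM with diluent and 115 ± 44.1 CPM with prexasertib, LYZ at 514 ± 121 and 3630 ± 733 CPM and MMP9 at 0.534 ± 0.152 and 51.7 ± 20.6 CPM. Of 27 such markers 24 rose and 0 fell (24 and 0 adjusted over the list alone) in ML1 (median 2.53, camera adjusted p = 2.4e-12, and 0.11 with an estimated correlation). In U937 12 rose and 2 fell (12 and 3 adjusted over the list alone) (median 0.50, camera adjusted p = 0.027, and 0.47 with an estimated correlation), with CD14 higher (2.38 ± 0.40), and 1 fell without diluent replicate 1 or 3 or prexasertib replicate 1 or 2. Myeloid progenitor and granule genes had no camera call in ML1 or U937 (adjusted p = 0.16 and 0.21). In ML1 3 rose and 8 fell (3 and 8 adjusted over the list alone) of 20, with FLT3 and MYB lower (-1.67 ± 0.20 and -1.29 ± 0.18), and in U937 3 rose and 6 fell (3 and 6 adjusted over the list alone), where median and mean differed in sign (-0.37 and 0.01). In U937, 0 rose without diluent replicate 2 or 3, 0 rose and 0 fell without prexasertib replicate 2, and the median was -0.24 without diluent replicate 1. In ML1, 5 rose without diluent replicate 1. Ribosome biogenesis and MYC targets in ML1 included FBL at 219 ± 11.9 and 97.4 ± 18.7 CPM, and of 24 1 rose and 21 fell (1 and 21 adjusted over the list alone) (median -0.75, camera adjusted p = 1e-05, and 0.47 with an estimated correlation). In U937 1 rose and 3 fell (0 and 0 adjusted over the list alone) (median -0.26, camera adjusted p = 0.027, and 0.75 with an estimated correlation). That camera call ended without diluent replicate 2 (0.2, median -0.14) or prexasertib replicate 1 (0.34), the median was -0.39 without diluent replicate 1, and 6, 0 and 1 fell without diluent replicates 1, 2 and 3 and 1, 0 and 10 without prexasertib replicates 1, 2 and 3.

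Cholesterol synthesis genes fell in part in both lines, with TMEM97 and FDPS lower in ML1 (-2.39 ± 0.23 and -1.39 ± 0.22) and LSS lower in U937 (-0.65 ± 0.17). Of 21 such genes 0 rose and 13 fell (0 and 14 adjusted over the list alone) in ML1 (median -0.61, camera adjusted p = 0.00089, and 0.61 with an estimated correlation) and 0 rose and 6 fell (0 and 8 adjusted over the list alone) in U937 (median -0.53, camera adjusted p = 0.00055, and 0.59 with an estimated correlation). In U937, 2 fell without diluent replicate 3, and 1 fell without prexasertib replicate 2 (median -0.30). Of 15 NRF2 targets 11 rose and 1 fell (11 and 1 adjusted over the list alone) in ML1, with the ferritin genes FTH1 and FTL higher (3.0 ± 0.23 and 1.66 ± 0.16, median 1.24, camera adjusted p = 0.00084, and 0.37 with an estimated correlation). In U937 3 rose and 1 fell (3 and 1 adjusted over the list alone), with no camera call (adjusted p = 0.99). In the BCL2 family, PMAIP1, the gene of NOXA, rose in both lines (5.31 ± 0.38 in ML1 and 2.57 ± 0.34 in U937, and 1.94 without U937 prexasertib replicate 2), and so did MCL1 (0.94 ± 0.16 in U937) and BBC3 (3.81 ± 0.22 in ML1). Of 16 family members 7 rose and 2 fell (7 and 3 adjusted over the list alone) in ML1 and 6 rose and 1 fell (6 and 1 adjusted over the list alone) in U937, with no camera call (adjusted p = 0.14 and 0.28). On adding LSN622666 0 rose and 8 fell (0 and 8 adjusted over the list alone) (median -0.36, camera adjusted p = 0.032, and 0.13 with an estimated correlation). The camera call ended without prexasertib replicate 3 (0.093), and 5 fell without prexasertib replicate 2 or combination replicate 3.

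Of the genes named in this part, BBC3, FDPS, FTH1, LSS, LYZ, MCL1, MMP9, MYB and TMEM97 share exonic positions with another annotated gene, so their values are uncertain to that extent.

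Of 9 tested markers of non-myeloid cells, 2 rose and 0 fell (3 and 0 adjusted over the list alone) in U937 (camera adjusted p = 0.035, and 0.28 with an estimated correlation, with no call without diluent replicate 2 or prexasertib replicate 1 at 0.099 and 0.091) and 1 rose and 2 fell (1 and 2 adjusted over the list alone) in ML1 (camera adjusted p = 0.86). COL1A2 had 153 counts over the U937 prexasertib group and 0 with diluent, at least 43.9-fold higher, and VWF had 41 against 3, a ratio of 11.8 with a 95% counting interval of 3.75 to 59.4. The VWF call ended without U937 diluent replicate 1 or 3 (adjusted p = 0.08 and 0.057) or prexasertib replicate 2 (0.099).

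More genes were detected in U937 with prexasertib than with diluent (20328 ± 647 against 18030 ± 353). Depth is argued against, since on counts thinned to the smallest library total the lowest prexasertib library had 1301 more detected genes than the highest diluent library. Uniform background reads in proportion to exonic length would leave 18.6% of 7684 silent genes without a count, and 46.2% had none, a ratio of 2.48 (2.39 to 2.57). Silent genes were picked by low diluent values, so diluent is low by selection. In U937 they held 245 to 879 CPM with prexasertib (highest in replicate 2), 89 to 155 with the combination and 32.2 to 48.4 with diluent. In ML1 prexasertib and diluent gave 228 to 396 and 29.3 to 31.4. Uneven background and transcription of normally silent genes under prexasertib may each account for these reads, and no test separates them.

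In U937, 525 genes were higher in the combination than in both other groups without a call for prexasertib alone, and 215 were lower. The numbers were 270 and 98 without diluent replicate 2, 305 and 122 without diluent replicate 3 and 193 and 56 without combination replicate 1, and 79 were lower without combination replicate 3. With replicate as a block they were 864 and 556. On thinned counts 93.1% of the 525 still passed, which argues against depth. They had a median GC content of 59.9%, against 48.4% in other genes, and after correcting each library for its trend on GC content and length 261 of 480 (54.4%) passed in both comparisons, with a median log2 fold change against prexasertib of 0.853 (quartiles 0.58 to 1.27) in place of 0.987 (0.716 to 1.39). Against prexasertib 426 of the 480 kept the call and against diluent 270, where the median went from 0.958 (0.666 to 1.41) to 0.696 (0.422 to 1.17). A GC-related bias of the libraries and an effect of LSN622666 on GC-rich genes cannot be told apart for these genes, because the correction removes both. The design has no group with LSN622666 alone, so an effect of this compound by itself may be part of the pattern and was not tested.

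The real grouping was compared with the other splits of the same libraries. In each comparison of 3 against 3 libraries there are 10 splits, too few for a share under 0.05, and 1 of the 10, the real one, called as many genes. The real values were 5369 for U937 prexasertib, 8419 for ML1, 4995 for the combination against prexasertib, 1895 against diluent and 10586 for the lines with diluent. The highest other split called 0 genes by edgeR's quasi-likelihood test in each of them. At an unadjusted p under 0.05 the highest other splits had 2952, 1009, 2735, 2089 and 704 genes, where the real ones had 7398, 9412, 7006, 4904 and 11180, and no other tool was run on the splits.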
